A study of Homo sapiens with 24 samples.

How the data were processed

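The submitters deposited 1 table of gene counts per cell line, and the counts were the authors' own. Each table holds 25168 genes for 12 libraries, with a gene length in kilobases that served only for the length check. Per the submitters' processing notes, STAR 2.7.8a, Partek, DESeq2, GRCh38 and hg38 were named, without the role or the order of each. Per the labels' protocols, cells were kept in low-glucose DMEM with serum, total RNA was taken with RNeasy and libraries were made with the KAPA mRNA Hyper Prep kit. The counting tool, the annotation release and the strand setting are not given in the sources used here. In BXPC3, the third SR4 column carries a number that differs from that of its sample title, so it was kept as an unnumbered replicate. Every value column was used. Coordinates came from RefSeq on GRCh38 p-release 14.

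Counts were scaled by TMM in edgeR 4.0.16 and genes were kept by filterByExpr with a minimum count of 10, which left 12920 genes in BXPC3 and 12514 in PANC1. TMM factors lay between 0.971 and 1.04 in BXPC3 and between 0.964 and 1.04 in PANC1. The biological coefficient of variation was 3.95% and 3.79%. Within groups, the spread of replicates over that of counting error, as chi-square per degree of freedom, was 1.31 to 3.40 and 1.35 to 3.77. A model of 4 groups per line with 8 residual degrees of freedom was tested by edgeR's quasi-likelihood test, with Benjamini-Hochberg adjustment at 0.05. A model of all 24 libraries in 8 groups gave the differences between lines. The SE of a log2 change was its size over the square root of the F statistic. Log2 CPM values for the principal components used a prior count of 2.

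Gene lists were fixed before the data were examined, and lists with at least 5 tested members were tested by camera in limma 3.58.1 on voom values with a preset correlation of 0.01. Camera's p-values were adjusted over the lists of a comparison. Of 914 list entries 55 were matched through RefSeq synonyms and 16 were not matched, 13 of them mitochondrially encoded. The tables hold 0 genes of the mitochondrial chromosome, so the planned share of mitochondrially encoded counts could not be computed.

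Genes were named by a rule. For each treatment against vehicle in each line these were the 5 largest rises and 5 largest falls among genes past the threshold with a mean log2 CPM of at least 2 over 12 libraries, where every treated library lay on the same side of every vehicle library. Up to 4 members with the smallest adjusted p were named per called list, and a fixed panel of energy, stress, cell cycle and sterol genes was added. For the interactions the 5 most positive and 5 most negative genes were taken without the library-by-library criterion. A gene was taken to respond in opposite directions when both lines passed with opposite signs and the difference between lines passed. Some genes that met these rules are not reported here, and they remain in all counts and list tests.

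Alternatives were DESeq2 size factors, the test of DESeq2 1.42.0, no low-count filter, the replicate number as a block, only the groups compared, an estimated correlation between genes in camera, a mean log2 CPM of at least 2 for the correlations across genes, and leaving out each library. Work was done in R 4.3.3. The pipeline was tested on simulated data, where 12568 genes were tested for BXPC3, 12229 for PANC1 and 11507 for both lines. Changes of each size were planted in 100 genes per line and test, and in 92 genes (0.5 log2) and 93 genes (1 log2) between lines. For SR4 against vehicle it recovered 79% of changes of 0.5 log2 and 96% of changes of 1 log2 in BXPC3, and 78% and 92% in PANC1. For the interaction it recovered 57% and 84% in BXPC3 and 59% and 86% in PANC1. For the difference between lines under SR4 it recovered 68.5% and 87.1%. False calls numbered 12 of 187 in BXPC3 and 13 of 183 in PANC1 for SR4, 13 of 154 and 6 of 151 for the interaction, and 16 of 299 between lines. Far fewer genes were changed in the simulation than the real comparisons called, so these figures may not hold for the data.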

Results

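RNA was sequenced from 2 human pancreatic cancer cell lines, BXPC3 and PANC1, that had been given vehicle, SR4 at 5 uM, lonidamine at 300 uM or both compounds for 24 h. SR4 is known by this code name as a mitochondrial uncoupler. Lonidamine is known to block the mitochondrial pyruvate carrier, monocarboxylate export and respiratory complex II. The series title gives the purpose as a pair of treatments aimed at the energy supply of pancreatic cancer cells. Each line had 4 groups of 3 libraries, so 24 libraries were compared in 8 groups. The labels do not state the doses within the combination separately. Comparisons of the combination with each compound alone, and departures from the sum of their changes, assume the same doses. Total gene counts, in units of 1e6 counts, lay between 9.14 and 11.5 per library in BXPC3 and between 8.87 and 11.8 in PANC1. In BXPC3 the mean totals were 11.04 ± 0.504 for vehicle, 10.3 ± 0.589 for SR4, 10.2 ± 0.407 for lonidamine and 9.25 ± 0.112 for the combination (SD, n = 3 each). In PANC1 they were 9.13 ± 0.360, 9.78 ± 0.0423, 11.1 ± 0.721 and 10.9 ± 0.663 in the same order (SD, n = 3 each).

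The lines kept markers that set them apart. SMAD4, a tumour suppressor known to be deleted in BXPC3, had 0 counts in every BXPC3 library, which allows up to 0.328 CPM (counts per) in the shallowest library. In PANC1 vehicle libraries it stood at 51.4 ± 1.89 CPM (SD, n = 3). CDH1, the epithelial cadherin, stood at 528 ± 23.001 CPM in BXPC3 vehicle libraries and at 17.5 ± 2.60 CPM in those of PANC1 (SD, n = 3 each). VIM, a mesenchymal filament protein, stood at 64.7 ± 2.65 and 4199.8 ± 48.4 CPM (SD, n = 3 each). Markers of other cell types were low or rested on single genes. CD68 was the highest of 12 immune markers, at 18.2 CPM in BXPC3 vehicle libraries and 123 CPM in PANC1. COL1A1, the highest of 10 fibroblast markers, went in PANC1 from 81.9 CPM with vehicle to 12.2, 31.3 and 16.2 CPM with SR4, lonidamine and the combination. In BXPC3 the sum over 8 endothelial markers went from 12.1 ± 0.932 CPM with vehicle to 1.37 ± 0.759 CPM with the combination (SD, n = 3 each), and that over 12 acinar markers from 13.5 ± 0.719 to 2.67 ± 0.484 CPM.

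Libraries of a group lay close together and the groups lay apart. The first principal component of log2 CPM carried 67.6% of the variance in BXPC3 and 59.5% in PANC1, and ran from vehicle to the combination in both lines. The second carried 13.4% and 18.4% and set the lonidamine libraries apart. Values after ± are standard errors (SE) for log2 changes and standard deviations (SD) for CPM, with n = 3 libraries in every group.

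**Figure D1:**
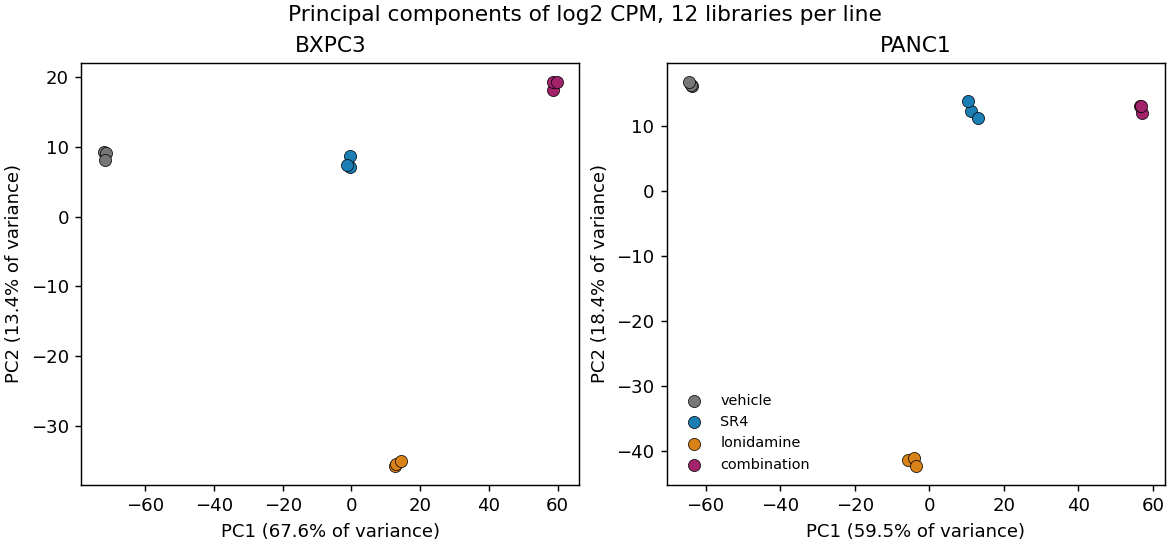
Each point is 1 library on the first principal components of log2 CPM (unitless scores; percent of variance on the axes), coloured by treatment, with BXPC3 on the left and PANC1 on the right. The 3 libraries of each group sit together, with vehicle at the low end of the first component (-71.9 to -71.3 in BXPC3) and the combination at the high end (58.6 to 59.7).

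With SR4 alone in BXPC3, the question was which genes respond to the uncoupler. TRIB3, a pseudokinase known to be induced by ATF4 and CHOP, rose by 4.43 ± 0.051 log2 (SE, n = 3 per group), from 24.9 ± 2.63 to 535 ± 11.8 CPM (SD). ALDH1L2, a mitochondrial folate enzyme, rose by 5.13 ± 0.13 log2, from 1.40 ± 0.140 to 49.5 ± 3.84 CPM. TYMS, which makes thymidylate, fell by 3.65 ± 0.078 log2, from 105 ± 1.16 to 8.39 ± 1.02 CPM, and CCNB1, the cyclin of mitotic entry, fell by 1.93 ± 0.045 log2. Of 12920 genes tested, 4310 rose and 4375 fell, of which 769 and 917 changed by at least 2-fold. TRIB3 had an adjusted p of 7.25e-29 and TYMS one of 1.51e-23 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

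The largest rises were in INHBE, an activin subunit gene, by 6.56 ± 0.34 log2, OSCAR, a collagen receptor gene, by 6.12 ± 0.26, ALDH1L2, NEURL1, a ubiquitin ligase gene, by 4.84 ± 0.35, and TRIB3. Over the 3 vehicle libraries INHBE had 4 counts, NEURL1 7 and OSCAR 8. Folds of INHBE, NEURL1 and OSCAR in BXPC3, here and below, rest on few vehicle counts and are uncertain in size. Among the largest falls were those of FAM111B, a replication-linked protease gene, by 4.06 ± 0.088 log2 (fell from 114 ± 4.17 to 6.75 ± 0.692 CPM), TYMS, ZNF488 and CCNE2, the G1/S cyclin, which fell by 3.47 ± 0.14. On GRCh38, TRIB3 lies on chromosome 20, 362835 to 397559, ALDH1L2 on chromosome 12, 105019784 to 105084577, INHBE on chromosome 12, 57452323 to 57459280, OSCAR on chromosome 19, 54094668 to 54102692, FAM111B on chromosome 11, 59107185 to 59127410 and TYMS on chromosome 18, 657604 to 673578.

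Of 35 ATF4 target genes of the integrated stress response, 34 rose and 1 fell, with a median change of 1.94 log2 (camera, adjusted p = 6.55e-23; adjusted p = 0.00127 with an estimated correlation). DDIT3, which encodes CHOP, rose by 3.75 ± 0.083, ASNS, asparagine synthetase, by 3.35 ± 0.049, SLC7A11, the cystine importer, by 3.07 ± 0.048, and ATF4 itself by 0.92 ± 0.034 log2. All 35 genes of G1/S and DNA replication fell, with a median of -2.13 (adjusted p = 1.64e-04 with an estimated correlation). MCM4 of the replicative helicase fell by 2.13 ± 0.041, PCNA, the polymerase clamp, by 2.28 ± 0.045 and RRM2, a ribonucleotide reductase subunit, by 3.18 ± 0.070 log2. All 37 genes of G2/M and mitosis fell, with a median of -1.85 (adjusted p = 0.00258 with an estimated correlation), TOP2A from 563 ± 14.3 to 142 ± 6.14 CPM. Of 22 genes of nucleotide synthesis, 17 fell and none rose (adjusted p = 0.00258 with an estimated correlation).

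All 18 genes of the tricarboxylic acid cycle fell, with a median of -0.54 (adjusted p = 0.0311 with an estimated correlation), SDHA of complex II by 0.80 ± 0.038 and OGDH by 0.80 ± 0.042 log2. Of 37 genes of complex I, 30 fell, with a median of -0.40 (adjusted p = 0.0446 with an estimated correlation). All 20 genes of complexes III and IV fell (adjusted p = 0.0666 with an estimated correlation), and 13 of 15 genes of ATP synthase fell (adjusted p = 0.0633 with an estimated correlation), ATP5G3 by 1.27 ± 0.050 log2. Of 23 genes of glycolysis, 5 rose and 14 fell, with a median of -0.39 (adjusted p = 0.192 with an estimated correlation). HK2, the hexokinase bound to mitochondria, rose by 0.51 ± 0.049 while LDHA, lactate dehydrogenase, fell by 1.53 ± 0.034, from 973 ± 4.16 to 337 ± 3.42 CPM. SLC16A3, the lactate exporter MCT4, rose by 0.17 ± 0.046 log2. MPC1 of the mitochondrial pyruvate carrier rose by 0.42 ± 0.14, with an adjusted p of 0.0123 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. This adjusted p was over 0.05 in 3 of 10 alternatives. It was 0.0509 without vehicle replicate 3, 0.0725 with the replicate number as a block and 0.0778 without the unnumbered SR4 replicate. The block gave the unnumbered library a level of its own, which in effect left it out, so these alternatives overlap.

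Of 25 targets of NRF2, the antioxidant regulator, 21 rose and 3 fell, with a median of 0.99 (adjusted p = 0.0365 with an estimated correlation). The ferritin genes FTH1 and FTL rose by 1.80 ± 0.030 and 1.87 ± 0.031, and HMOX1, heme oxygenase, by 3.04 ± 0.12 log2. Of 29 genes of autophagy and lysosomes, 20 rose (adjusted p = 0.00911 with an estimated correlation), SQSTM1 by 2.05 ± 0.031 and MAP1LC3B by 1.76 ± 0.039. Cytosolic heat shock genes fell, 14 of 16 (adjusted p = 0.0311 with an estimated correlation), HSP90AA1 by 0.77 ± 0.031, and so did proteasome genes, 25 of 31 (adjusted p = 0.0366 with an estimated correlation). Of 29 interferon response genes 22 fell and 3 rose (adjusted p = 0.260 with an estimated correlation), among them CXCL10, which fell from 78.0 ± 7.05 to 13.2 ± 0.460 CPM. Of 25 genes of cholesterol synthesis 12 rose and 4 fell, with a median of 0.18 (adjusted p = 0.101 with an estimated correlation). INSIG1, a sterol sensor, rose by 0.80 ± 0.036 log2. The list named nuclear-retained RNAs also holds the snoRNA host gene GAS5, and where its RNAs lay in the cell was not measured. It moved with the treatment, 7 of 8 rising (adjusted p = 0.146 with an estimated correlation), and its sum went from 595 ± 29.5 to 1357 ± 283 CPM (SD, n = 3 each). In all, 24 of 38 lists were called (10 up, 14 down) and 11 were called with an estimated correlation. Over all list entries 697 of 817 changed, against 700 adjusted over the list alone, and 22 of the 24 called lists had identical counts either way. The call of the immediate early genes, 12 of 22 rising (adjusted p = 0.146 with an estimated correlation), was lost without SR4 replicate 1.

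The origin of the 3 replicates of a group, such as separate cultures, is not given in the sources used here, so p-values measure only the spread between these samples, which may be technical. An exact permutation of 3 against 3 libraries has 10 splits and cannot go below 0.1, and counting intervals and floors cover counting error only. Whether the counts separate reads of close paralogs, such as FTH1 and its copies, or of antisense neighbours is not known. The counting tool and the strand setting are not given in the sources used here.

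Lonidamine alone in BXPC3 addressed the response to the metabolic inhibitor. ASNS rose by 3.81 ± 0.049 log2 (SE, n = 3 per group), from 33.6 ± 1.80 to 471 ± 22.6 CPM (SD), and TXNIP, a glucose-responsive brake on glucose uptake, rose by 2.40 ± 0.039 log2, from 99.0 ± 3.997 to 521 ± 15.0 CPM. CYP24A1, the vitamin D hydroxylase, fell by 6.74 ± 0.31 log2, from 15.5 ± 1.40 to 0.131 ± 0.114 CPM. It had 4 counts over the 3 lonidamine libraries, so its fold is uncertain in size. CXCL10, an interferon-induced chemokine gene, fell by 4.47 ± 0.10 log2. Of 12920 genes, 4502 rose and 4221 fell, of which 695 and 1254 changed by at least 2-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 2.23e-28 for ASNS and 5.27e-23 for CXCL10.

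OSCAR, ALDH1L2, ADM2, an ATF4 target, CYP1A1, the aryl hydrocarbon receptor target, and NEURL1 rose most. Their log2 changes were 6.501 ± 0.25, 5.29 ± 0.12, 4.64 ± 0.11, 4.29 ± 0.15 and 4.11 ± 0.39. CYP1A1 stood at 1.79 ± 0.0933 CPM with vehicle, 1.996 ± 0.534 with SR4 and 35.3 ± 2.66 with lonidamine (SD, n = 3 each). CYP24A1, TRIM31, FAM111B and ORC1 of the origin recognition complex were among the largest falls, and ORC1 fell by 5.36 ± 0.15 log2. CYP24A1 lies on chromosome 20, 54153449 to 54173973, NEURL1 on chromosome 10, 103493979 to 103592552 and ASNS on chromosome 7, 97852118 to 97872542.

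ATF4 targets rose, 34 of 35, with a median of 2.19 (adjusted p = 0.00142 with an estimated correlation). TRIB3 rose by 4.10 ± 0.051, PSAT1 of serine synthesis by 2.93 ± 0.037 and SLC7A5, a leucine importer, by 2.39 ± 0.036 log2. All 35 G1/S genes fell, with a median of -2.81 (adjusted p = 1.64e-04 with an estimated correlation), and 36 of 37 G2/M genes fell, with a median of -2.78 (adjusted p = 0.00299 with an estimated correlation). CCNB1 fell by 2.73 ± 0.049, TOP2A by 3.46 ± 0.050 and MCM7 by 2.87 ± 0.048, while CDKN1A, the cell cycle inhibitor p21, rose by 1.74 ± 0.037 log2. Nucleotide synthesis genes fell, 18 of 22 (adjusted p = 0.00299 with an estimated correlation), RRM2 by 4.28 ± 0.081. Interferon genes fell, 27 of 29, with a median of -1.90 (adjusted p = 0.114 with an estimated correlation), OAS3 from 238 ± 29.2 to 22.997 ± 1.08 CPM. YAP targets rose, 15 of 18 (adjusted p = 0.0308 with an estimated correlation), with F3, tissue factor, up by 0.65 ± 0.027 and CYR61, a matricellular protein gene, up by 0.84 ± 0.035; adjusted over the list alone 15 rose and 3 fell. Immediate early genes rose, 16 of 22 (adjusted p = 0.0308 with an estimated correlation), KLF4 by 1.51 ± 0.054 log2.

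Among energy genes, HK2 rose by 1.12 ± 0.048 and LDHA fell by 1.07 ± 0.034 log2, and all 15 genes of ATP synthase fell, with a median of -0.48 (adjusted p = 0.0908 with an estimated correlation). The list of glucose-sensing targets of MondoA also holds MLXIP, the gene of MondoA itself. Of its 6 genes 4 rose (adjusted p = 0.103 with an estimated correlation), ARRDC4 by 2.63 ± 0.089 log2. HMGCS1, the entry enzyme of the mevalonate pathway, fell by 0.62 ± 0.036 log2. The cholesterol list was not called, with 10 up and 11 down of 25 (camera, adjusted p = 0.730). In all, 18 of 38 lists were called (8 up, 10 down), 6 of them also with an estimated correlation. Of 817 entries 669 changed, against 674 adjusted over the list alone, and 15 called lists had identical counts. The nuclear-retained list was not called (camera, adjusted p = 0.0941), with a sum of 1635 ± 610.3 CPM (SD, n = 3).

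The combination in BXPC3 asked what both compounds did together against vehicle. INSIG1 rose by 2.94 ± 0.036 log2 (SE, n = 3 per group), from 146 ± 2.32 to 1121 ± 8.24 CPM (SD), and HMGCS1 by 1.94 ± 0.035, from 356 ± 14.8 to 1365 ± 4.45 CPM. NDRG1, a gene induced by low oxygen and iron loss, rose by 4.76 ± 0.039, from 67.5 ± 2.93 to 1827 ± 26.9 CPM. CCNB1 fell by 3.78 ± 0.056 and CYR61 fell by 2.25 ± 0.043 log2. Of 12920 genes, 5127 rose and 5102 fell, of which 1645 and 1948 changed by at least 2-fold. NDRG1 had an adjusted p of 1.09e-32 and INSIG1 one of 3.31e-29 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

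OSCAR, NEURL1, IL13RA2, a decoy receptor gene, TRIB3 and ALDH1L2 rose most, by 7.74 ± 0.21, 5.90 ± 0.30, 5.27 ± 0.26, 5.09 ± 0.051 and 4.91 ± 0.13 log2. IGFBP5, ZNF488 and FAM111B were among the largest falls, and IGFBP5, an insulin-like growth factor carrier, fell by 7.21 ± 0.12 log2 from 253 ± 13.5 to 1.70 ± 0.737 CPM. CYP24A1 had 2 counts over the 3 combination libraries, a ratio to vehicle of 0.00478 (95% counting interval 0.000577 to 0.0173). NDRG1 lies on chromosome 8, 133237171 to 133302022, INSIG1 on chromosome 7, 155297776 to 155310235 and HMGCS1 on chromosome 5, 43289395 to 43313512.

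Of 25 genes of cholesterol synthesis 24 rose and none fell, with a median of 1.63 log2 (camera, adjusted p = 4.95e-13; adjusted p = 0.00124 with an estimated correlation). MSMO1 rose by 2.52 ± 0.037 and CYP51A1 by 1.98 ± 0.033. Of 16 genes of fatty acid synthesis 12 rose (adjusted p = 0.124 with an estimated correlation), ACSS2, which makes acetyl-CoA from acetate, by 3.24 ± 0.041 and SCD, the stearoyl desaturase, by 1.61 ± 0.026. Hypoxia targets rose, 15 of 19 (adjusted p = 0.0333 with an estimated correlation), LOX by 3.25 ± 0.084 and VEGFA by 2.38 ± 0.069 log2. ATF4 targets rose, 33 of 35 with a median of 2.06 (adjusted p = 0.00294 with an estimated correlation), with 2 rather than 1 falling when adjusted over the list alone, DDIT3 to 198 ± 4.52 CPM. The list of metallothioneins, which bind metal ions, also holds the zinc transporter gene SLC30A1. Of its 7 genes 6 rose (adjusted p = 0.0333 with an estimated correlation), MT1G by 3.58 ± 0.15. NRF2 targets rose in 19 of 25 cases (adjusted p = 0.0742 with an estimated correlation), FTH1 from 1583 ± 72.2 to 11611 ± 177 CPM.

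All 35 G1/S genes fell, with a median of -2.92 (adjusted p = 7.77e-04 with an estimated correlation), and 36 of 37 G2/M genes fell, with a median of -3.94 (adjusted p = 0.00730 with an estimated correlation). TOP2A fell by 4.87 ± 0.058 to 19.3 ± 1.05 CPM and CDKN1A rose by 2.43 ± 0.037 log2. Interferon genes fell, 25 of 29 (adjusted p = 0.166 with an estimated correlation), CXCL10 by 6.07 ± 0.13. Ribosome biogenesis genes fell, 24 of 28 (adjusted p = 0.0300 with an estimated correlation), TCOF1 by 2.23 ± 0.049 log2. YAP targets went both ways, 6 up and 11 down of 18 (adjusted p = 0.118 with an estimated correlation), and ANKRD1 fell by 3.02 ± 0.066. Genes of the tricarboxylic acid cycle fell, all 18 (adjusted p = 0.0333 with an estimated correlation), as did 32 of 37 of complex I (adjusted p = 0.0333 with an estimated correlation), all 20 of complexes III and IV (adjusted p = 0.0462 with an estimated correlation) and 14 of 15 of ATP synthase (adjusted p = 0.0454 with an estimated correlation), or all 15 adjusted over the list alone. MPC1 rose by 1.42 ± 0.13, HK2 rose by 0.96 ± 0.049 and LDHA fell by 0.90 ± 0.034 log2. The nuclear-retained list rose beside these groups, 7 of 8 (adjusted p = 0.154 with an estimated correlation), with a sum of 2229 ± 240.4 CPM (SD, n = 3). In all, 26 of 38 lists were called (13 up, 13 down), 17 of them with an estimated correlation. Of 817 entries 747 changed, against 750 adjusted over the list alone, and 23 called lists had identical counts.

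Against each compound alone, the combination in BXPC3 showed what the second compound added, if the doses matched. These list tests were added after the data had been seen. Against SR4, cholesterol synthesis genes rose, 24 of 25 with a median of 1.41 (adjusted p = 2.73e-04 with an estimated correlation), and G2/M genes fell, 36 of 37 with a median of -2.14 (adjusted p = 0.00671 with an estimated correlation). Hypoxia targets rose, 16 of 19 (adjusted p = 0.00846 with an estimated correlation), and interferon genes fell, 25 of 29 (adjusted p = 0.132 with an estimated correlation). Against lonidamine, cholesterol synthesis genes rose, 24 of 25 with a median of 1.61 (adjusted p = 2.29e-04 with an estimated correlation), and YAP targets fell, 17 of 18 with a median of -1.11 (adjusted p = 0.00449 with an estimated correlation). G2/M genes fell, 32 of 37 (adjusted p = 0.0270 with an estimated correlation), and NRF2 targets rose, 18 of 25 (adjusted p = 0.0406 with an estimated correlation). ER chaperone and ERAD genes, which handle misfolded proteins, rose, 19 of 24 (adjusted p = 0.0270 with an estimated correlation). CYR61 stood at 235 ± 2.91, 138 ± 0.447, 419 ± 10.9 and 49.4 ± 1.31 CPM with vehicle, SR4, lonidamine and the combination (SD, n = 3 each). HMOX1 went from 9.70 ± 0.320 CPM with lonidamine to 53.2 ± 1.99 CPM with the combination. Against SR4, 3919 genes rose and 3937 fell, 380 and 959 by at least 2-fold, and against lonidamine 3893 rose and 3967 fell, 644 and 661 by at least 2-fold. The calls covered 18 lists against SR4 and 21 against lonidamine, or 8 and 12 with an estimated correlation. Entries changed numbered 642 and 644, against 645 and 652 adjusted over the list alone.

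The interaction in BXPC3 asked whether the combination departed from the sum of the log2 changes of the single compounds. ASNS departed by -3.75 ± 0.063 log2 and TRIB3 by -3.43 ± 0.065 (SE, n = 3 per group). ASNS stood at 343 and 471 CPM with SR4 and lonidamine alone and at 358 CPM with the combination. HMGCS1 departed by 2.30 ± 0.050 and FDPS, farnesyl diphosphate synthase, by 2.34 ± 0.059, FDPS standing at 168 ± 5.28, 116 ± 3.69, 101.5 ± 2.48 and 357 ± 8.06 CPM with vehicle, SR4, lonidamine and the combination. The adjusted p was 2.85e-25 for ASNS and 1.02e-22 for HMGCS1 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. Of 12920 genes, 3061 lay above the sum and 3298 below it, 730 and 671 by at least 2-fold.

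The genes farthest above were STC1, a glycoprotein hormone gene, by 5.86 ± 0.14, ORC1, IL1RL1, the interleukin-33 receptor, by 4.44 ± 0.083, PCLAF and CDT1, a replication licensing factor. STC1 stood at 26.5 ± 1.74, 3.32 ± 0.359, 8.09 ± 0.0930 and 59.1 ± 1.54 CPM in the 4 groups, so it fell with each compound and rose with both. Those farthest below were INHBE, ALDH1L2, OSCAR, ADM2 and SYBU, with INHBE at -5.98 ± 0.55 and ALDH1L2 at -5.51 ± 0.15. STC1 lies on chromosome 8, 23841915 to 23854807 and IL1RL1 on chromosome 2, 102311502 to 102352037.

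Of 35 ATF4 targets 34 lay below the sum, with a median of -1.99 (camera, adjusted p = 6.73e-32; adjusted p = 2.09e-04 with an estimated correlation). Of 25 cholesterol genes 23 lay above it, with a median of 1.35 (adjusted p = 8.87e-05 with an estimated correlation), and so did 34 of 35 G1/S genes, with a median of 1.98 (adjusted p = 8.87e-05 with an estimated correlation), and 31 of 37 G2/M genes (adjusted p = 0.0313 with an estimated correlation). Adjusted over the list alone, the G1/S and G2/M counts were 35 and 32. With vehicle, SR4, lonidamine and the combination, the G1/S list totalled 3923 ± 42.4, 917 ± 6.11, 625 ± 12.6 and 610 ± 10.8 CPM. The G2/M list totalled 6985 ± 159, 2034 ± 40.8, 1367 ± 36.6 and 921 ± 20.5 CPM. These totals were not higher with the combination than with either compound alone. Lying above thus meant a smaller fall than both log2 falls together. The log scale was not tested for these lists. All 18 YAP targets lay below the sum, with a median of -0.96 (adjusted p = 8.52e-04 with an estimated correlation), CYR61 at -2.32 ± 0.057. LDHA lay above it, at 1.69 ± 0.048. In all, 20 of 38 lists were called (13 up, 7 down) and 6 with an estimated correlation. Of 817 entries 573 changed, against 582 adjusted over the list alone. The call of hypoxia targets, 12 above and 6 below of 19 (adjusted p = 0.198 with an estimated correlation), was lost with DESeq2 size factors and without vehicle replicate 2, lonidamine replicate 2, lonidamine replicate 3 or SR4 replicate 2.

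**Figure D2:**
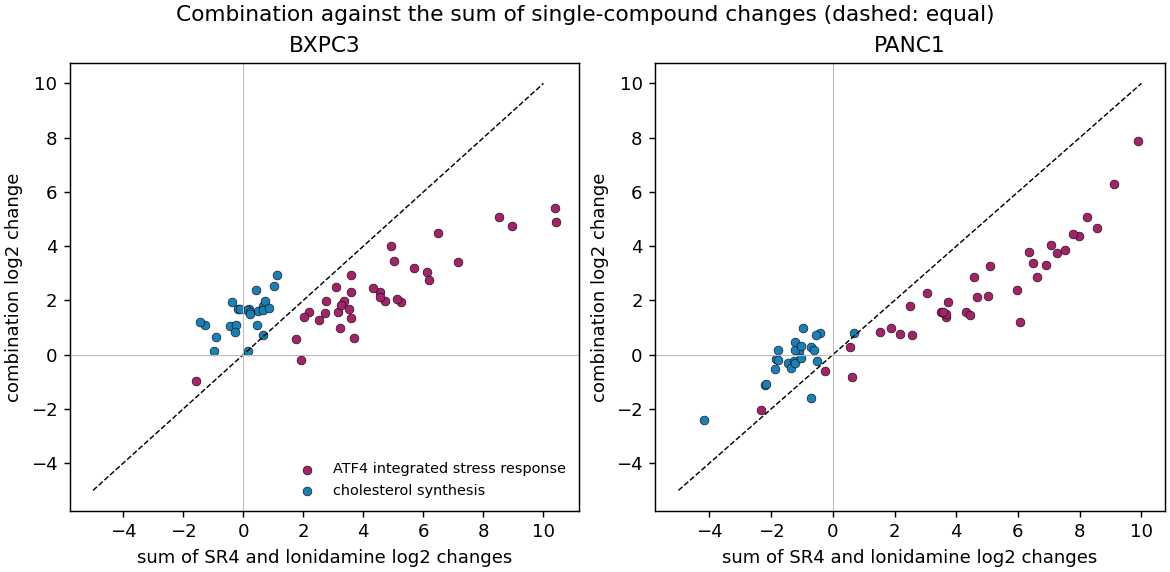
Each point is 1 gene, with the sum of its SR4 and lonidamine log2 changes on the x axis and its log2 change with the combination on the y axis, for ATF4 targets and cholesterol synthesis genes in each line; the dashed line marks equality. In BXPC3 34 of 35 ATF4 targets passed the test below the line and 23 of 25 cholesterol genes passed it above the line.

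SR4 and lonidamine changed an overlapping set of genes in BXPC3. Called in the same direction by both were 6656 genes, 3321 up and 3335 down, and 346 were called in opposite directions. Independent lists of these sizes would share 1502 up and 1429 down. The correlation of the log2 changes across genes was 0.811, and genes are not independent replicates. In 20 simulations of unchanged groups with shared vehicle libraries, all drawn anew, there was at most 1 shared call. With no gene changed, few calls were fixed in advance, so that count does not bear on the shared controls. The simulations gave a mean correlation of 0.489 and a mean covariance of 0.0166, at most 0.0191. The observed covariance was 0.569, so the spread between vehicle libraries accounts for little of it. A shift common to all 3 vehicle libraries was not simulated, and its share cannot be told. The 3 vehicle libraries are too few to split and shared calls were not simulated with changed genes. Part of the excess of calls over independent lists may therefore come from the shared controls.

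SR4 alone in PANC1 put the same question, the response to the uncoupler, to the second line. HSPA5, the ER chaperone BiP, rose by 3.16 ± 0.031 log2 (SE, n = 3 per group), from 767 ± 27.4 to 6838 ± 44.1 CPM (SD), and ATF3, a stress transcription factor, rose by 5.68 ± 0.061, from 7.84 ± 0.995 to 405 ± 6.34 CPM. CTGF, a matricellular protein gene and YAP target, rose by 3.45 ± 0.048, from 232 ± 4.18 to 2532 ± 148 CPM. HMGCS1 fell by 1.41 ± 0.052 log2, from 129 ± 6.58 to 48.5 ± 1.33 CPM. HK2 rose by 3.96 ± 0.089, from 6.09 ± 1.02 to 95.0 ± 1.86 CPM. Of 12514 genes, 4376 rose and 4596 fell, 1045 and 1057 by at least 2-fold. HSPA5 had an adjusted p of 4.32e-32 and HMGCS1 one of 2.39e-19 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

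CCND2, cyclin D2, rose most, by 6.06 ± 0.32 log2, followed by ATF3, HKDC1, a hexokinase-like gene, by 5.35 ± 0.21, RAB39B by 5.25 ± 0.12 and BEX4 by 5.21 ± 0.31. Over the 3 vehicle libraries CCND2 had 4 counts and BEX4 had 6. Folds of CCND2 and BEX4 in PANC1, here and below, rest on few vehicle counts and are uncertain in size. Among the largest falls, FAM111B fell by 3.98 ± 0.11, ADAMTS15, a matrix protease gene, by 3.35 ± 0.097, EGR1, an immediate early factor, by 3.13 ± 0.16 and SLC2A12 by 2.91 ± 0.18. CCND2 lies on chromosome 12, 4273772 to 4305350, ATF3 on chromosome 1, 212565334 to 212620777, CTGF on chromosome 6, 131948176 to 131951373 and HK2 on chromosome 2, 74833981 to 74893359.

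Of 36 ATF4 targets 33 rose and 3 fell, with a median of 2.19 log2 (camera, adjusted p = 6.33e-17; adjusted p = 0.0199 with an estimated correlation). TRIB3 rose by 4.81 ± 0.057, ASNS by 3.34 ± 0.050 and CHAC1, a glutathione-degrading enzyme gene, by 3.81 ± 0.098. G1/S genes fell, 34 of 35 with a median of -0.99 (adjusted p = 0.0199 with an estimated correlation), GINS1 by 2.38 ± 0.075. G2/M genes fell, 35 of 37 with a median of -0.81 (adjusted p = 0.0541 with an estimated correlation), CCNB1 by 1.25 ± 0.043. Of 24 cholesterol synthesis genes 23 fell and none rose, with a median of -1.10 (adjusted p = 0.0773 with an estimated correlation); adjusted over the list alone 23 fell and 1 rose. Fatty acid synthesis genes fell, 14 of 16 (adjusted p = 0.172 with an estimated correlation), FASN by 1.41 ± 0.039, and 1 rose when adjusted over the list alone. Hypoxia targets rose, 16 of 21 (adjusted p = 0.281 with an estimated correlation), VEGFA by 2.62 ± 0.062 and ADM by 1.88 ± 0.053. YAP targets rose, 13 of 18 (adjusted p = 0.0501 with an estimated correlation), CYR61 from 605 ± 19.7 to 3043 ± 187 CPM, and immediate early genes rose, 15 of 20 (adjusted p = 0.0541 with an estimated correlation), MYC by 1.60 ± 0.042. Cytosolic tRNA synthetase genes rose, 15 of 19 (adjusted p = 0.0501 with an estimated correlation), AARS by 2.21 ± 0.035.

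LDHA fell by 0.56 ± 0.045 and SLC16A3 by 1.27 ± 0.045 log2, the latter from 355 ± 7.93 to 147 ± 10.2 CPM. PDK1, which restrains pyruvate dehydrogenase, rose by 1.08 ± 0.069 and MPC1 by 0.89 ± 0.12. Of 15 ATP synthase genes 14 fell, with a median of -0.36 (adjusted p = 0.293 with an estimated correlation), and of 18 tricarboxylic acid cycle genes 12 fell (adjusted p = 0.331 with an estimated correlation). TXNIP fell by 0.77 ± 0.35 with an adjusted p of 0.0495 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and was past the threshold in none of 10 alternatives, with adjusted p from 0.0516 to 0.132. The nuclear-retained list rose, 7 of 9 (adjusted p = 0.141 with an estimated correlation), and its sum went from 1072 ± 147 to 2839 ± 588 CPM (SD, n = 3 each). Its snoRNA host gene GAS5 rose by 2.56 ± 0.045, and whether its RNA stayed in the nucleus was not measured. In all, 22 of 37 lists were called (11 up, 11 down) but 2 with an estimated correlation, namely ATF4 targets and G1/S genes. Of 785 entries 658 changed, against 663 adjusted over the list alone, and 19 called lists had identical counts.

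Lonidamine alone in PANC1 asked which genes respond to the metabolic inhibitor in this line. NGFR, the low-affinity neurotrophin receptor, rose by 6.12 ± 0.23 log2 (SE, n = 3 per group), from 0.768 ± 0.0223 to 54.0 ± 13.1 CPM (SD), and SESN2, a sestrin induced by starvation, rose by 3.90 ± 0.060, from 12.9 ± 1.36 to 192 ± 3.25 CPM. ELF3, an epithelial transcription factor, fell by 3.67 ± 0.16, from 22.2 ± 1.94 to 1.75 ± 0.383 CPM, and TOP2A fell by 1.99 ± 0.036, from 973 ± 12.6 to 246 ± 10.9 CPM. Of 12514 genes, 4381 rose and 4278 fell, 819 and 1017 by at least 2-fold. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p was 2.59e-19 for NGFR and 1.10e-17 for ELF3.

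NGFR, CCND2, BEX4, LAMP3 and KLHDC7B rose most, LAMP3, a lysosomal membrane protein gene, by 5.22 ± 0.088 and CCND2 by 5.77 ± 0.33. KLHDC7B had 5 counts over the 3 vehicle libraries, so its fold is uncertain too. DHRS3, a retinal reductase gene, RASL11A, GPRC5B, ELF3 and FAM111B fell most, DHRS3 by 3.87 ± 0.11. NGFR lies on chromosome 17, 49495293 to 49515017, ELF3 on chromosome 1, 202007945 to 202017188 and KLHDC7B on chromosome 22, 50548033 to 50551023. ATF4 targets rose, 34 of 36 with a median of 2.28 (adjusted p = 0.00897 with an estimated correlation), TRIB3 by 3.73 ± 0.058, ASNS by 3.15 ± 0.049 and SLC7A11 by 4.01 ± 0.093. All 35 G1/S genes fell, with a median of -1.88 (adjusted p = 0.00845 with an estimated correlation), MCM4 by 2.56 ± 0.050, and G2/M genes fell, 36 of 37 with a median of -1.78 (adjusted p = 0.0273 with an estimated correlation), CCNB1 by 1.93 ± 0.044. The p53 target list rose, 15 of 22 (adjusted p = 0.128 with an estimated correlation), with SESN2, TNFRSF10B, a death receptor gene, up by 2.06 ± 0.045, and GADD45A up by 0.97 ± 0.073. PANC1 is known to carry a p53 mutation, and SESN2 is also on the ATF4 list. CDKN1A rose by 0.47 ± 0.056.

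Of 22 genes of glycolysis 15 fell and 3 rose (adjusted p = 0.479 with an estimated correlation), and LDHA fell by 1.16 ± 0.046, PGAM1 by 0.87 ± 0.039 and SLC16A3 by 1.28 ± 0.044. HK2 rose by 2.25 ± 0.11 and SLC2A1, the glucose importer GLUT1, by 1.42 ± 0.062. Of 18 tricarboxylic acid cycle genes 15 fell (adjusted p = 0.244 with an estimated correlation), IDH2 by 1.20 ± 0.063, and of 15 ATP synthase genes 14 fell (adjusted p = 0.244 with an estimated correlation). Nucleotide synthesis genes fell, 15 of 22 (adjusted p = 0.0945 with an estimated correlation), and heat shock genes fell, 14 of 16 (adjusted p = 0.244 with an estimated correlation). MPC2 had a log2 change of -0.21 ± 0.091, with an adjusted p of 0.0443 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment that ranged from 0.0110 to 0.320 over the alternatives and was lost without lonidamine replicate 3, vehicle replicate 1 or vehicle replicate 3 and with DESeq2's test. The nuclear-retained list was not called (camera, adjusted p = 0.0812), with a sum of 2058 ± 359 CPM (SD, n = 3). In all, 18 of 37 lists were called (5 up, 13 down), 3 of them with an estimated correlation. Of 785 entries 637 changed, against 640 adjusted over the list alone, and 17 called lists had identical counts.

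The combination in PANC1 asked what both compounds did together in this line. HSPA5 rose by 3.74 ± 0.032 log2 (SE, n = 3 per group), from 767 ± 27.4 to 10264 ± 79.0 CPM (SD), and HERPUD1, an ERAD gene, by 4.196 ± 0.062, from 19.5 ± 2.06 to 359 ± 1.93 CPM. LDHA fell by 2.43 ± 0.049, from 1582 ± 36.6 to 293 ± 14.9 CPM, and SLC16A3 fell by 2.37 ± 0.049, from 355 ± 7.93 to 68.5 ± 4.32 CPM. HK2 rose by 4.25 ± 0.086 and MPC1 by 2.85 ± 0.094, MPC1 from 9.41 ± 1.10 to 67.6 ± 2.92 CPM. Of 12514 genes, 5022 rose and 5121 fell, 1756 and 2062 by at least 2-fold. HSPA5 had an adjusted p of 8.76e-34 and LDHA one of 9.43e-26 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

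CCND2 rose most, by 6.85 ± 0.28 log2, then NGFR, BEX4, RAB39B and MFSD2A, a lysolipid transporter gene, which rose by 6.32 ± 0.18 from 0.687 ± 0.473 to 56.5 ± 4.57 CPM. The largest fall was in ADAMTS15, which fell by 5.92 ± 0.13, then ELF3 by 5.46 ± 0.21, LRFN1, HAS3, a hyaluronan synthase gene, by 5.10 ± 0.23, and SLC2A12. LDHA lies on chromosome 11, 18394388 to 18408425, SLC16A3 on chromosome 17, 82228397 to 82261129 and MPC1 on chromosome 6, 166364919 to 166383013. ATF4 targets rose, 33 of 36 with a median of 2.16 (adjusted p = 0.0569 with an estimated correlation), ATF3 by 6.27 ± 0.059 and DDIT3 by 4.06 ± 0.055. ER chaperone and ERAD genes rose, 20 of 24 with a median of 1.14 (adjusted p = 0.200 with an estimated correlation), HSP90B1 by 1.55 ± 0.031. Cytosolic tRNA synthetase genes rose, 16 of 19 with a median of 0.92 (adjusted p = 0.0569 with an estimated correlation). Glycolysis genes fell, 16 of 22 with a median of -1.01 (adjusted p = 0.384 with an estimated correlation), PGAM1 by 1.74 ± 0.041. G1/S genes fell, 34 of 35 with a median of -1.10 (adjusted p = 0.0569 with an estimated correlation), and G2/M genes fell, 36 of 37 with a median of -1.13 (adjusted p = 0.0874 with an estimated correlation), CCNB1 by 1.66 ± 0.044. Mesenchymal markers fell, 14 of 16 (adjusted p = 0.0874 with an estimated correlation), S100A4 by 2.32 ± 0.056 and MMP2, a matrix protease gene, by 2.35 ± 0.068. Epithelial markers were not called, with 6 up and 12 down of 18 and a median of -1.15 (camera, adjusted p = 0.0900). Ribosome biogenesis genes rose, 17 of 28 (adjusted p = 0.353 with an estimated correlation), RRP12 by 1.76 ± 0.039, while NCL, nucleolin, fell by 0.77 ± 0.032.

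All 15 ATP synthase genes fell (adjusted p = 0.287 with an estimated correlation), ATP5G3 by 1.77 ± 0.057, while CYCS, cytochrome c, rose by 0.70 ± 0.038 among complexes III and IV, of which 17 of 20 fell (adjusted p = 0.321 with an estimated correlation). The cholesterol list was not called, with 11 up and 13 down of 24 (camera, adjusted p = 0.634). The nuclear-retained list rose beside these groups, 7 of 9 (adjusted p = 0.247 with an estimated correlation), with a sum of 2745 ± 38.5 CPM (SD, n = 3). In all, 17 of 37 lists were called (5 up, 12 down), and 0 were called with an estimated correlation. Of 785 entries 694 changed, against 692 adjusted over the list alone, and all 17 called lists had identical counts. The proteasome call, 21 of 31 falling (adjusted p = 0.471 with an estimated correlation), was lost with DESeq2 size factors, with the replicate number as a block, and without vehicle replicate 1 or 3, combination replicate 1 or any of the 3 lonidamine replicates.

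Set against each compound alone in PANC1, the combination showed what the second compound added, if the doses matched. These list tests were also added after the data had been seen. Against SR4, glycolysis genes fell, 21 of 22 with a median of -0.90 (adjusted p = 0.228 with an estimated correlation), and hypoxia targets fell, 19 of 21 (adjusted p = 0.228 with an estimated correlation). YAP targets fell, 14 of 18 with a median of -0.76 (adjusted p = 0.0110 with an estimated correlation), and mesenchymal markers fell, 13 of 16 (adjusted p = 0.0423 with an estimated correlation). Cholesterol genes rose, 22 of 24 (adjusted p = 0.0749 with an estimated correlation), and ER chaperone genes rose, 23 of 24 (adjusted p = 0.0749 with an estimated correlation). Against lonidamine, ER chaperone genes rose, 22 of 24 (adjusted p = 0.244 with an estimated correlation), and glycolysis genes fell, 17 of 22 (adjusted p = 0.583 with an estimated correlation). G2/M genes stood higher with the combination than with lonidamine, 33 of 37 with a median of 0.52 (adjusted p = 0.292 with an estimated correlation), TPX2, a spindle factor, at 308 ± 12.5 CPM with lonidamine and 753 ± 16.1 CPM with the combination. CTGF stood at 232 ± 4.18, 2532 ± 148, 270.2 ± 18.6 and 745 ± 33.0 CPM with vehicle, SR4, lonidamine and the combination (SD, n = 3 each). Against SR4, 4150 genes rose and 4174 fell, 482 and 821 by at least 2-fold, and against lonidamine 4642 rose and 4696 fell, 905 and 1186 by at least 2-fold. The calls covered 14 lists against SR4 and 9 against lonidamine, or 2 and 0 with an estimated correlation. Entries changed numbered 626 and 612, against 632 and 614 adjusted over the list alone.

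The interaction in PANC1 asked the same of this line, the departure from the sum of the single-compound changes. GDF15, a stress cytokine gene, departed by -4.85 ± 0.076 log2 (SE, n = 3 per group), standing at 28.8 ± 1.54, 253 ± 12.7, 219.9 ± 7.67 and 66.7 ± 4.02 CPM (SD) with vehicle, SR4, lonidamine and the combination. TRIB3 departed by -3.89 ± 0.072 and VEGFA by -2.95 ± 0.083. AURKA, the mitotic kinase, departed by 1.84 ± 0.062 and HMGCS1 by 1.69 ± 0.069. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the adjusted p of GDF15 was 9.66e-27 and that of AURKA 1.17e-19. Of 12514 genes, 3858 lay above the sum and 3760 below it, 831 and 1036 by at least 2-fold.

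EGR1, E2F2, FAM111B, RAB26 and FEN1, the flap endonuclease, lay farthest above, FEN1 by 2.82 ± 0.11. KLHDC7B, HKDC1, CCND2, THBD, thrombomodulin, and GDF15 lay farthest below, HKDC1 by -5.06 ± 0.27. Of 36 ATF4 targets 34 lay below the sum, with a median of -2.41 (camera, adjusted p = 2.25e-25; adjusted p = 0.00601 with an estimated correlation). All 35 G1/S genes lay above it, with a median of 1.55 (adjusted p = 0.00601 with an estimated correlation), and so did 36 of 37 G2/M genes, with a median of 1.42 (adjusted p = 0.0278 with an estimated correlation). YAP targets lay below it, 12 of 18 (adjusted p = 0.0278 with an estimated correlation), CTGF at -1.99 ± 0.064. Hypoxia targets lay below it, 17 of 21 (adjusted p = 0.136 with an estimated correlation), or 18 adjusted over the list alone, and cholesterol genes lay above it, 22 of 24 with a median of 1.18 (adjusted p = 0.0667 with an estimated correlation). SLC2A1 departed by -2.43 ± 0.081 and HK2 by -1.96 ± 0.12. With vehicle, SR4, lonidamine and the combination, the G1/S list totalled 3536 ± 13.3, 1617 ± 37.8, 952 ± 28.1 and 1419 ± 18.8 CPM. The G2/M list totalled 9475 ± 195, 5610 ± 93.5, 3022 ± 133 and 4530 ± 78.3 CPM. Both lists thus stayed below vehicle with the combination, between the single compounds. The log scale was not tested for these lists. In all, 22 of 37 lists were called (10 up, 12 down), 4 of them with an estimated correlation. Of 785 entries 602 changed, against 610 adjusted over the list alone. The calls of NF-kB genes, 8 of 15 below (adjusted p = 0.120 with an estimated correlation), and replication-dependent histones, 6 of 8 below (adjusted p = 0.200 with an estimated correlation), were lost without the low-count filter.

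SR4 and lonidamine overlapped less in PANC1 by the counts alone, a difference that was not tested. Called in the same direction by both were 5823 genes, 2823 up and 3000 down, with 949 in opposite directions, against 1532 up and 1571 down for independent lists. The correlation across genes was 0.720 and the covariance 0.491. Simulated unchanged groups gave 0 shared calls, which the lack of changed genes fixed in advance, and a mean correlation of 0.528. Their mean covariance was 0.0199, at most 0.0229, so the spread between vehicle libraries accounts for little of the observed covariance. A shift common to the vehicle libraries was not simulated here either. Part of the excess of shared calls may come from the shared controls here too.

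**Figure D3:**
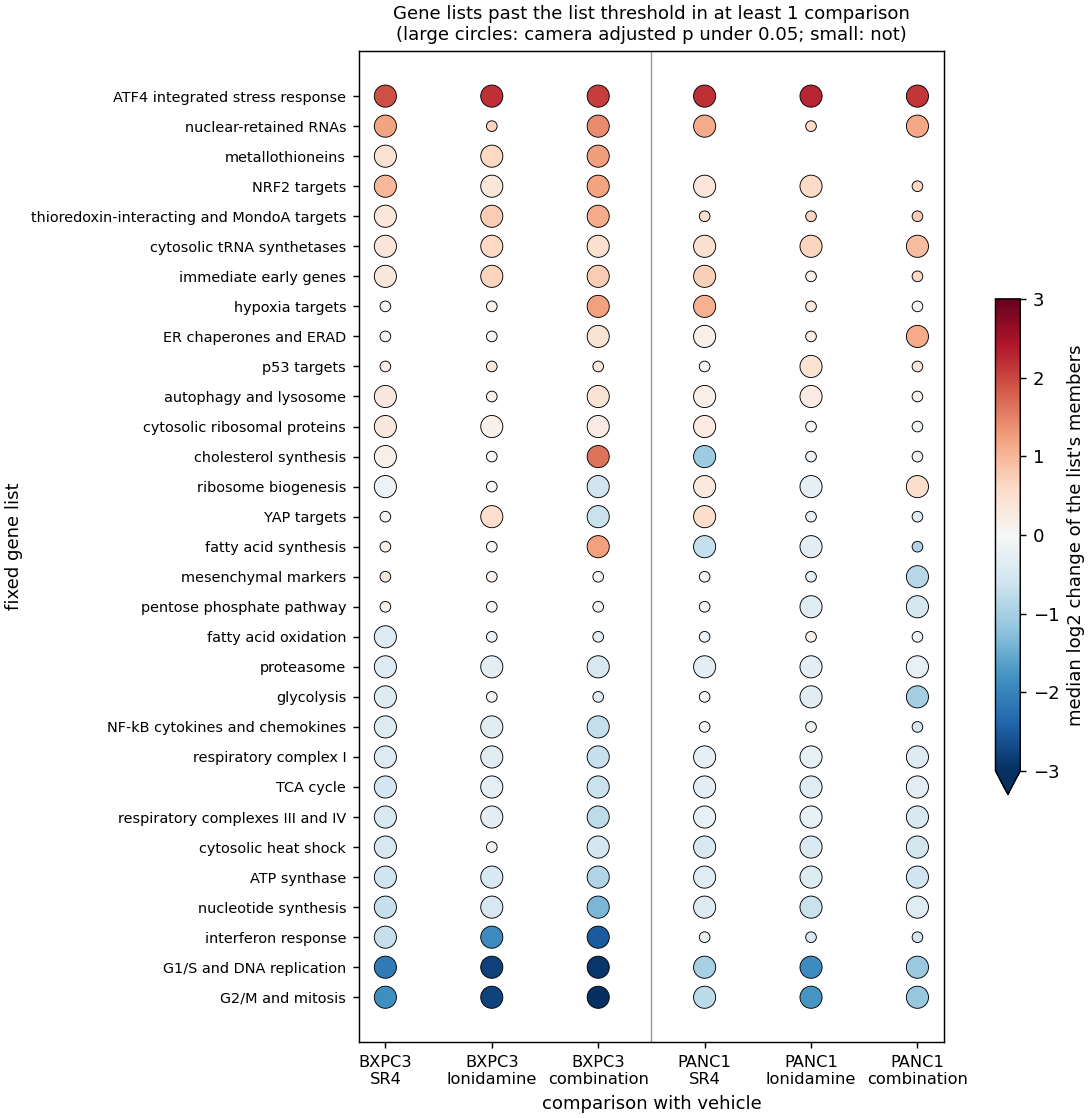
Circles give the median log2 change of each fixed gene list (colour scale in log2 units) for 3 treatments against vehicle in each line, large where camera's adjusted p was under 0.05 with the preset correlation. Medians of ATF4 targets ran from 1.94 to 2.28, while those of cholesterol genes ran from -1.10 with SR4 in PANC1 to 1.63 with the combination in BXPC3.

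The last comparisons asked where the lines responded differently, as PANC1 minus BXPC3 in 1 model of all 24 libraries. With SR4, HMGCS1 changed by 0.27 in BXPC3 and -1.41 in PANC1, a difference of -1.67 ± 0.062 log2 (SE, n = 3 per group). CYR61 changed by -0.76 and 2.33, a difference of 3.10 ± 0.055. With the combination, NDRG1 changed by 4.75 and -0.34, a difference of -5.09 ± 0.11, and SLC16A3 by 0.63 and -2.42, a difference of -3.05 ± 0.069. NDRG1 had an adjusted p of 4.88e-31 for the difference by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment.

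Of 13930 genes, 7126 differed in their response to SR4 (51.2%; 3656 higher and 3470 lower in PANC1), 5817 to lonidamine (41.8%; 3277 and 2540) and 8617 to the combination (61.9%; 4410 and 4207). Differences of at least 2-fold numbered 1811, 1489 and 3352. Genes called in opposite directions in the lines, with the difference also called, numbered 1360, 913 and 1971. List tests of these differences were added after the data had been seen. In them, higher or lower in PANC1 refers to the log2 change against vehicle and not to the level. With SR4, 24 of 25 cholesterol genes were lower in PANC1, with a median of -1.28 (adjusted p = 0.00245 with an estimated correlation), and all 37 G2/M genes were higher, with a median of 1.01 (adjusted p = 0.00371 with an estimated correlation). With lonidamine, 36 of 37 G2/M genes were higher in PANC1 (adjusted p = 0.00202 with an estimated correlation), and of 19 YAP targets 13 were lower (adjusted p = 0.00202 with an estimated correlation). The cholesterol list was not called with lonidamine, 6 higher and 8 lower (camera, adjusted p = 0.216). With the combination, 22 of 25 cholesterol genes were lower in PANC1, with a median of -1.74 (adjusted p = 0.00416 with an estimated correlation). G2/M genes were higher, 36 of 37 with a median of 2.86 (adjusted p = 0.00416 with an estimated correlation), as were ribosome biogenesis genes, 25 of 28 with a median of 1.09 (adjusted p = 0.00416 with an estimated correlation). Of 39 lists 16, 14 and 21 were called for SR4, lonidamine and the combination, or 7, 3 and 8 with an estimated correlation.

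Across 11538 genes tested in both lines, the log2 changes of the lines had Pearson correlations of 0.504 for SR4, 0.602 for lonidamine and 0.512 for the combination, and Spearman correlations of 0.478, 0.581 and 0.516. These are correlations across genes, which are not independent replicates. Both lines called 2289, 2671 and 3003 genes up, against 1425, 1504 and 1984 for independent lists, and 2405, 2455 and 2849 down, against 1432, 1254 and 1787. The lines share no libraries.

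**Figure D4:**
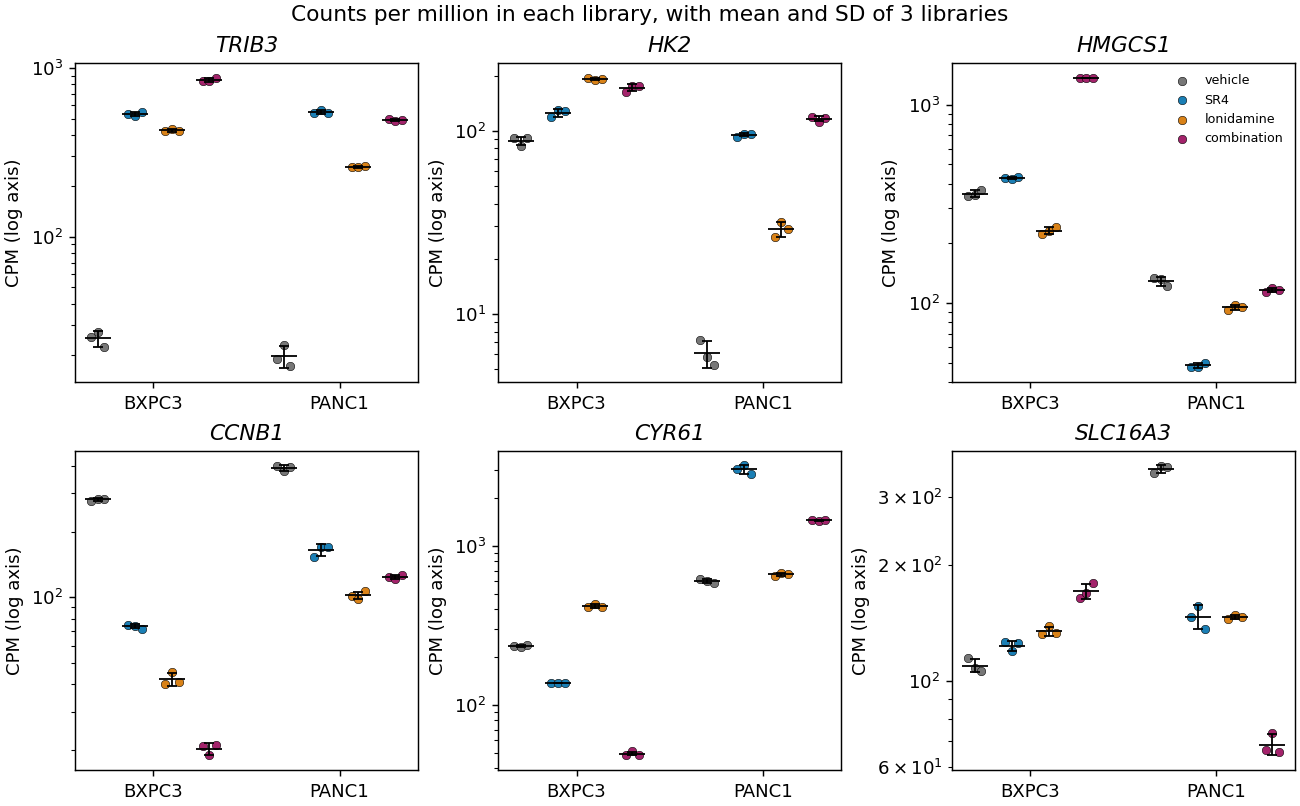
Each point is the CPM of 1 library (log axis) for 6 genes in both lines, coloured by treatment, with bars for the mean and SD of 3 libraries. TRIB3 rose and CCNB1 fell with every treatment in both lines, while HMGCS1, CYR61 and SLC16A3 moved in opposite directions between the lines under at least 1 treatment.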

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

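The rule that names genes and the thresholds were chosen before the data were examined, the patterns discussed further on were chosen after the results were seen, and no test in this part was added.

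The response differed in size or direction between lines for 7126 genes with SR4, 5817 with lonidamine and 8617 with the combination. Of these, 1360, 913 and 1971 were called in opposite directions. In the separate models of the lines, over 11538 genes, both lines called 2289, 2671 and 3003 genes up and 2405, 2455 and 2849 down, while 697, 532 and 986 were up in BXPC3 and down in PANC1 and 634, 350 and 889 the reverse. Pairs of a named gene and a treatment found to have 3 counts or fewer in a compared group were left out. Counts were screened in the line where a gene was named, and in both lines only for genes named for a line difference. The PANC1 counts of OASL, ANKRD1, CXCL8 and SPRY4, for example, were not screened. Among named genes in the pairs kept, 49 passed the threshold in opposite directions in the model of all 24 libraries. They made 64 gene and treatment pairs, 24 with SR4, 12 with lonidamine and 28 with the combination. The PANC1 call of TXNIP with SR4 was lost in all 10 alternatives, with adjusted p from 0.0516 to 0.132 by edgeR's or DESeq2's test with Benjamini-Hochberg adjustment. The BXPC3 call of PDK1 with lonidamine was lost without vehicle replicate 2 or lonidamine replicate 3, with adjusted p of 0.0787 and 0.0728 by edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment. In the separate PANC1 model, the fall of CDKN1A with the combination was not called. It passed only without vehicle replicate 3, with an adjusted p of 0.0491 by the same test. Values are given for most of these pairs, as the log2 change against vehicle in PANC1 minus that in BXPC3. Lower or higher in PANC1 therefore refers to the change and not to the level. The pairs that met the same rule but were left out of these counts and values for low counts numbered 6. Some pairs that were kept also rest on few counts. CCND2 had 4 counts over the 3 PANC1 vehicle libraries and CAPN12 had 4 over the 3 BXPC3 vehicle libraries. Over the 3 PANC1 libraries of each group, TMEM45B had 25 counts with vehicle and 11 with lonidamine. The sizes of the differences of these genes are therefore uncertain.

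With SR4, the changes of these genes of sterol synthesis and its control were lower in PANC1, HMGCS1 by -1.67, INSIG1 by -2.35, MSMO1 by -2.04 and CYP51A1 by -1.34. Differences were also found for CYR61 by 3.10, CTGF by 4.07, CXCL8 by 2.37, SOD2 by -1.25, ADM by 2.13 and CCND2 by 7.52. Lower in PANC1 were the changes of SLC16A3 by -1.45, TXNIP by -2.12, MLXIP by -0.73 and CDKN1A by -1.64. Higher in PANC1 were the changes of FBL by 0.76, POLR1B by 1.02, DDX21 by 0.71, CTPS1 by 1.80 and IMPDH2 by 0.85. Lower too were the changes of SLC30A1 by -0.95, MT1X by -1.22 and MT1E by -1.26.

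With lonidamine, SLC16A1 by -0.53, SLC16A3 by -1.54, PDK1 by 0.71 and MLXIP by -1.12 differed between the lines, and so did F3 by -1.12, AXL by -0.88, MT1E by -1.01, BAG3 by -0.96 and FASN by -1.52. The largest were NGFR by 7.65, CCND2 by 7.26 and TMEM45B by -4.41.

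With the combination, the changes that were lower in PANC1 were those of HMGCS1 by -2.13, INSIG1 by -3.52, ACSS2 by -3.68 and SCD by -2.57. Differences were found for SLC16A3 by -3.05, NDRG1 by -5.09, PGD by -1.50 and CYCS by 1.37. Others were CYR61 by 3.47, ANKRD1 by 5.04, ITGA5 by -2.91, COL5A1 by -2.10 and ELF3 by -5.85. RRP12 by 1.88, POLR1B by 1.90 and RPLP0 by -0.68 differed as well. The same held for CDKN1A by -2.58, SOD2 by -2.19, OASL by 4.73, PHLDA1 by -1.86, SPRY4 by -2.84, SLC30A1 by -1.20 and MT1E by -2.50. The largest were CCND2 by 11.53, NGFR by 7.56, BMF by -7.38 and CAPN12 by -6.06.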

How the results depend on the processing

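The alternatives were chosen before the data were examined, and the list tests of the combination against each compound and of the differences between lines were added after the results were seen.

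Every count of changed genes and both overlaps stayed within 1.5-fold of their size under every alternative that was run for them. The largest drop with DESeq2's test was in the BXPC3 interaction, from 6359 to 5530, and SR4 in BXPC3 went from 8685 to 7949. With an estimated correlation, camera called 11 lists for SR4, 6 for lonidamine, 17 for the combination and 6 for the interaction in BXPC3, against 24, 18, 26 and 20. In PANC1 it called 2, 3, 0 and 4, against 22, 18, 17 and 22. The estimated correlation between genes of a list widened the test, and the cause of the lost calls beyond this was not tested.

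With a mean log2 CPM of at least 2, the correlations across genes between lines were 0.534 for SR4, 0.670 for lonidamine and 0.529 for the combination. Leaving out 1 library moved them over 0.493 to 0.502 for SR4, 0.583 to 0.6005 for lonidamine and 0.503 to 0.512 for the combination, the lowest each time without PANC1 vehicle replicate 1. Without PANC1 SR4 replicate 3 the SR4 value was 0.494. The cause was not tested.

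Deviations from group means of samples with the same replicate number correlated by -0.0754 to 0.0775 over 15 pairs in BXPC3. In PANC1 they correlated by -0.135 to 0.0856 over 18 pairs, and 0 pairs in either line were over 0.1. No pairing by number was seen. Pairs with different numbers were not compared, so shared handling of same-numbered samples cannot be excluded. With the replicate number as a block, the changed genes numbered 7992 for SR4, 8595 for lonidamine, 10148 for the combination and 5758 for the interaction in BXPC3. In PANC1 the block gave 8917, 8603, 10104 and 7554. Between lines the block gave 6654, 5658 and 8534 for SR4, lonidamine and the combination. In BXPC3 the unnumbered SR4 library formed a block of its own and so added nothing to these estimates. Part of the lower numbers that involve SR4 in BXPC3 may come from that.

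Of 835 named gene comparisons, 13 took another label under at least 1 alternative, and no gene changed sign. Among them were MPC1, MPC2, TXNIP and PDK1. The planned share of mitochondrially encoded counts was not run, because the tables hold 0 such genes.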

Other observations

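The patterns and the tests of library scaling and of single libraries were chosen after the results were seen, while the tests of gene length, of the log scale and of the splits were written before their values were known.

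Some genes near the counting floor also moved. PRDM16, a chromatin regulator gene, had a ratio to vehicle of 28.0 (95% counting interval 7.37 to 237) with SR4 and 75.7 (20.5 to 632) with the combination in BXPC3. In PANC1, KRT17, a basal keratin gene, had a ratio of 58.3 (15.8 to 487) with the combination, and LCN2, an iron-binding lipocalin gene, one of 49.3 (8.52 to 1976) with lonidamine. NLRP1, an inflammasome sensor gene, stood at least 34.95-fold over vehicle with the combination, against a floor of 3 counts over the group.

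Cholesterol synthesis genes fell with SR4 in PANC1 (camera, adjusted p = 0.0773 with an estimated correlation, where the call was lost) and rose with the combination in BXPC3 (adjusted p = 0.00124 with an estimated correlation). The fall of -1.10 was -1.10 and -1.14 under other library scalings, -1.12 after the trend on gene length was removed (100% of members had a length) and -1.06 to -1.22 without 1 library. The rise of 1.63 was 1.57 and 1.62 under other scalings, 1.57 after the length trend was removed and 1.59 to 1.64 without 1 library. Gene length and a single library therefore do not account for either, while scaling factors between 0.964 and 1.04 left the scaling test little room to move a median. Cholesterol genes stood above the sum of the single-compound changes in both lines. These were 23 of 25 in BXPC3 (camera, adjusted p = 8.87e-05 with an estimated correlation) and 22 of 24 in PANC1 (adjusted p = 0.0667 with an estimated correlation). The lines differed in level. With vehicle, SR4, lonidamine and the combination, the list totalled 4235, 4645, 4092 and 12003 CPM in BXPC3. In PANC1 it totalled 3376, 1451, 2876 and 2893 CPM. There the combination stayed below vehicle and near lonidamine alone. The cause is left open.

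G2/M genes stood higher with the combination than with lonidamine alone in PANC1, by a median of 0.52. This was 0.46 and 0.53 under other scalings, 0.48 after the length trend was removed and 0.49 to 0.56 without 1 library, so gene length and a single library do not account for it, while the scaling test had little room to move it. The list was not called with an estimated correlation (camera, adjusted p = 0.292). The cause was not tested.

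ATF4 targets lay below the sum of the log2 changes, by medians of -1.99 in BXPC3 and -2.41 in PANC1, or -1.89 to -2.14 and -2.36 to -2.52 without 1 library. On the linear scale, 6 of 35 members in BXPC3 and 3 of 36 in PANC1 reached vehicle plus both single-compound increases, with median shares of 0.583 and 0.529 of that sum, and 17 and 14 stood above both single compounds. The log scale alone therefore does not account for the pattern. The cause was not tested.

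Splits of the libraries into other groupings were set beside the real ones. Other splits mixed libraries of different treatments within a group. That widened the spread within groups and left treatment differences in the contrasts, so these splits cannot settle whether chance gave a result. For each comparison of 3 against 3 libraries, 1 of 10 splits called as many genes, the real one, and the highest other called 0, but 10 splits are too few for a share under 0.05. The lists called were at most 20, 17 and 21 in other splits in BXPC3, against 24, 18 and 26 for SR4, lonidamine and the combination, and 16, 17 and 16 in PANC1, against 22, 18 and 17. For the interaction 1 of 100 splits called as many genes in each line, with the highest other at 5929 in BXPC3, against 6359, and 2517 in PANC1, against 7618. Lists called for the interaction reached the real 20 in 28 of 100 splits in BXPC3, the highest other 24, which neither excludes nor shows chance. In PANC1 the real number was reached in 1 of 100, the highest other 21 against 22.

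Between lines, 1, 1 and 1 of 100 splits called as many genes for SR4, lonidamine and the combination, the highest others 2464, 1494 and 1976. The correlation across genes was reached in 5 of 100 splits for SR4, the highest other 0.546 against 0.504. Treatment differences that the lines share stayed in these splits, so this share neither excludes nor shows chance. For lonidamine it was 1 of 100, the highest other 0.492 against 0.602, and for the combination 1 of 100, the highest other 0.503 against 0.512.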
